A study of Arabidopsis thaliana with 50 samples.

How the data were processed

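RNA from pools of the apical or basal parts of 7 leaves of 7-week-old plants, grown in 8 h of light per day, was sequenced in 50 libraries, 5 for each of 10 groups of line and leaf part. Samples were grouped by the genotype and leaf part that the labels give. Per the submitters' processing notes, base calls were converted with bcl2fastq, DESeq was used and the build was TAIR10; versions were not stated there. The file used holds 1 table of 18231 genes and 13 columns: 4 columns of the authors' deposited log2 fold changes of apical parts against wild-type apical parts, and the authors' deposited p-value for genotype, tissue and their interaction, each uncorrected and corrected, in 6 columns. The header of the deposited fold changes names no log base; base 2 was derived from the values, since low genes differ by exact steps of 0.2, which is 1 doubling in 1 of 5 libraries. The deposited p-values are per gene over all lines, not per comparison. The deposited corrected p-value times its rank, over the uncorrected p-value, gave 25801 as the number of genes tested, so the authors' correction was read as Benjamini-Hochberg over that number. Only genes with a corrected genotype p under 0.05 are listed, so genes that are not listed have no value here and every share is a share of listed genes. Depth is unknown, and no counting interval or detection limit was computed. Values per library were not used here, so no test of this series was refitted, no SD between libraries was computed and no other split of the samples could be run.

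Before the data were examined, the reading planned for a table of comparisons was a corrected p under 0.05. Since all 18231 listed genes pass it in every comparison, the reading reported is a log2 fold change of at least 1 in size (2-fold), which had been planned as a second reading. The 3 comparisons with b'γ are differences of 2 deposited values.

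The largest-error test was added after the data were seen. The uncorrected p-values of genotype and interaction were turned into F values with 4 and 40 degrees of freedom. For each gene, the 4 apical fold changes and both F values bound the residual variance, with line means taken to lie within 20 log2 units. The largest variance grows as the 2 F values approach each other, as they do where line differences lie in the apical parts alone. Such a gene can fail the test at a large change, so failing it is no evidence against a change. A contrast test with the largest variance so allowed was then adjusted by Benjamini-Hochberg over the 25801 genes tested. The degrees of freedom were checked on 147 genes at exactly 0 in 3 lines: F of genotype and interaction were equal within 2% for 73, and for 66 of these F of tissue was equal too, which holds when 1 group alone departs. The equal-parts test used the variance that follows if basal line differences are as large as apical ones. Tested on 25000 simulated genes, 0.0249% of largest-error calls had no true change. The rates that follow are for the 11382 simulated genes with a corrected genotype p under 0.05, and a call also needed the 2-fold limit. The test called 30.2% of their simulated changes of log2 1, 77.5% of log2 2 and 94.4% of log2 4. With the true variance and the same limit, 47.6% of changes of log2 1 were called. The true variance lay inside the bounds for 100% of listed genes. Each simulated gene had normal errors with the same SD in every group, and basal changes ranged from none to larger than the apical ones. These rates need not hold for genes at the floor in some lines, nor for changes of the apical parts alone.

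Gene lists (27, with 372 of 394 distinct genes listed) were fixed before the data were examined. Each direction of each list was tested with a one-sided Fisher's exact test against the other listed genes, with genes as units, and adjusted by Benjamini-Hochberg over the lists of a comparison and direction. Of 375 list entries, all pass the authors' corrected genotype p over all genes tested, and 374 pass when adjusted over the list alone. Levels are not part of the values used, so the planned matching of random lists on mean expression and the planned limit to the upper 50% by level could not be applied, and no percentile of a list is reported.

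Named genes followed a rule fixed before the data were examined: B'γ, B'ζ, ICS1, PR1 and SAG12 in every comparison; the 5 largest and 5 smallest log2 fold changes against wild type (3 and 3 against b'γ), each gene taken once; and the 3 members with the largest change of each list with at least 3 changed members. The level criterion of this rule was left out. Other members of the lists are named with their values where a group is described. Shared calls were set against n1 times n2 over the number of listed genes, and against 100 simulated sets of unchanged lines that share their wild-type pools, drawn with the variance of the equal-parts test and again with the largest one.

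Alternatives were no size limit, a corrected p under 0.01, an adjustment over listed genes, the largest-error and equal-parts tests, centring on the 6 listed reference genes and leaving out the chromosome 5 stretch. The stretch was found by a running median over 31 listed genes in chromosome order, against 200 shuffles of gene order. The highest windows of b'γζ and b'γ sid2, 1.08 and 1.1, lay in it and exceeded the largest shuffled ones, 0.41 and 0.67. In b'γ the highest window lay on chromosome 1, so the scan of that line did not single out the stretch. The 0.96 of the stretch in b'γ is a median of 164 genes, so the largest shuffled window of 31 genes, 1.55, is no measure of it. In b'γ 117 of the 164 genes were over 0.5, against 40 of 164 flanking genes. Its ends were those of the run of listed genes with the largest sum of the mean of b'γζ and b'γ sid2, limited to -1 to 2, less 0.5. Intervals of medians are 95% bootstrap intervals from 10000 resamples of genes. They measure the spread between genes and leave out the error between pools. Gene names and neighbour order came from the annotation TAIR10.1, which held 18153 of the identifiers; no positions are printed, since the submitters' build is named TAIR10. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.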

Results

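RNA was sequenced from the apical and basal parts of leaves of 7-week-old Arabidopsis thaliana plants of accession Col-0, in 25 apical and 25 basal libraries. The plants were wild type, a mutant in the B'γ regulatory subunit of protein phosphatase 2A (pp2a-b'γ, called b'γ here), a double mutant that also affects the B'ζ subunit (b'γζ), a double mutant with sid2, a lesion in the salicylic acid synthesis gene ICS1 (b'γ sid2), and a complemented b'γ line that carries B'γ behind a constitutive viral promoter. Each of the 10 groups of line and leaf part held 5 pools of 7 leaf parts. Per the labels, the apical parts of b'γ were yellowing with cell death, and its basal parts had no symptoms. The values were the authors' deposited log2 fold changes of the apical parts of each line against apical wild type, with p-values that the authors computed per gene over all lines for genotype, leaf part (tissue) and their interaction. Values per library were not used here, so a gene has no SD between libraries, and the depth of the libraries is unknown. The deposited table listed 18231 genes, each with an authors' corrected genotype p under 0.05.

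A gene was counted as higher or lower in a line when its deposited value was at least 2-fold from wild type. A stricter reading, called the largest-error test, used the largest residual variance that the deposited p-values allow for each gene, and "rose" and "fell" are kept for genes that passed both. All changes are on the log2 scale, and a gene that "fell to" a negative value had that log2 fold change or difference. A stretch of 164 listed genes on chromosome 5, from AT5G03406 to AT5G05250, was higher together in b'γ, b'γζ and b'γ sid2, with median log2 fold changes of 0.96, 1.0 and 1.02, and had a median of 0.01 in the complemented line. It was found and bounded by its values in b'γζ and b'γ sid2, where the highest running medians of 31 neighbouring listed genes lay in it. In b'γ the highest such window was centred on AT1G51760 on chromosome 1, with a median of 1.73, above the 1.55 of the largest window in 200 shuffles of gene order, and in the complemented line no window exceeded the largest shuffled one, 0.49. Counts without this stretch stand beside the counts for each line. Where a list call ended at a corrected genotype p under 0.01, with the largest-error test or after centring on the reference genes, this is said beside it. List calls without a size limit, the reading planned first, are given together near the end.

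**Figure D1:**
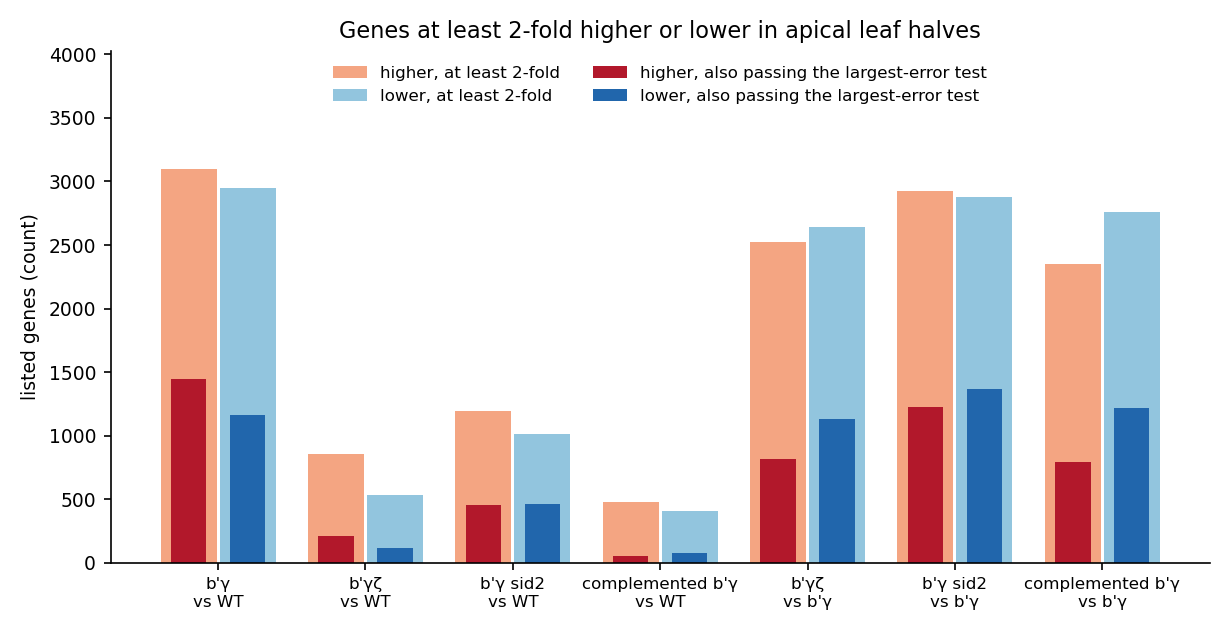
Listed genes at least 2-fold higher or lower (y axis, count) in each of the 7 comparisons of apical parts (x axis); the wide bars count all such genes and the narrow bars those that also passed the largest-error test. The b'γ line had 3099 higher and 2949 lower genes against wild type, and the complemented line 480 and 405.

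The first question was whether the transcripts that the labels name as disrupted were lower in their lines. B'ζ fell by 2.59 in b'γζ in the authors' deposited table, and its values were -0.40 in b'γ, -0.51 in b'γ sid2 and -0.26 in the complemented line. The deposited values of B'γ were -0.69 in b'γ, -0.46 in b'γζ and -0.72 in b'γ sid2, none of which passed the largest-error test, and 0.35 in the complemented line. Set against b'γ directly, B'γ rose by 1.04 in the complemented line. ICS1 had a deposited value of -0.97 in b'γ sid2 and rose by 3.18 in b'γ. Of the 18 genes for targets and PP2A subunits, 16 were listed, and 1 further subunit gene passed both criteria against wild type: B'η fell by 3.28 in the complemented line alone, and its deposited values in b'γ, b'γζ and b'γ sid2 were 0.16, 0.05 and -0.40.

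**Figure D2:**
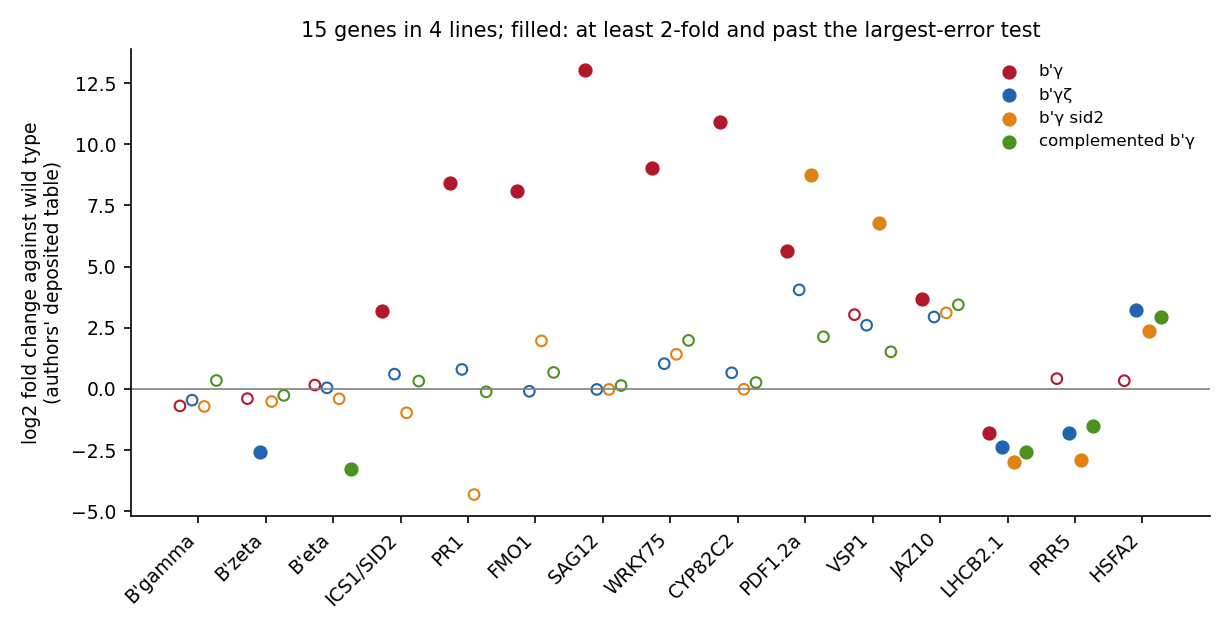
The authors' deposited log2 fold change against wild type (y axis) of 15 of the named genes (x axis), chosen for display after their values were seen, with 1 point per line; filled points were at least 2-fold from wild type and passed the largest-error test. PR1, SAG12, FMO1 and CYP82C2 stood above 8 in b'γ, while SAG12 lay within 0.15 of wild type in the other lines.

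The comparison of b'γ with wild type asked which genes differed in the symptomatic leaf parts. Genes on the lists for salicylic acid defence, leaf senescence, camalexin and protein folding in the endoplasmic reticulum were higher, and nuclear photosynthesis genes were lower. By the authors' deposited values, the α-dioxygenase DIOX1 rose by 13.24, SAG12, a cysteine protease of senescing leaves, by 13.02, the berberine bridge enzyme family gene AT1G26390 by 12.32, the β-glucosidase DIN2 by 11.79 and the pectinesterase AT2G45220 by 11.72. DIOX1 was listed at exactly 0 in b'γζ and b'γ sid2, as was DIN2 in b'γ sid2, so their values in b'γ were measured from the authors' floor. SAG12, PDF1.3, PDF1.2b and AT5G59732 had the same lowest value in 2 of the 4 lines, which also marks the floor, so their largest deposited values and differences depend on it too. CYP82C2 stood at 10.91 in b'γ and differed from it by -10.92 in b'γ sid2, so it may lie at the floor in that line as well. At the other end of the deposited table, the acyltransferase-like gene AT1G65450 fell to -6.42 and the pseudogene AT1G69140 to -5.99, and the values of AT1G54700 at -5.70, the lipid transfer family gene AT2G10940 at -5.40 and the xyloglucan transferase XTH6 at -5.16 did not pass the largest-error test.

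In all, 3099 listed genes were at least 2-fold higher and 2949 lower in b'γ, and 1442 and 1164 of them passed the largest-error test. Without the chromosome 5 stretch the counts were 3021 and 2945. After centring on the reference genes they were 2621 and 3685, so which direction had more genes depended on the scaling. The defence gene PR1 rose by 8.43 in the deposited table, FMO1, which acts in systemic acquired resistance, by 8.10 and the salicylic acid hydroxylase gene DLO1 by 5.82. Of the 31 listed genes of salicylic acid and systemic resistance, 26 were at least 2-fold higher, more than among other listed genes (one-sided Fisher's exact test, p = 8.48e-15 adjusted over the 27 lists). Leaf senescence genes were higher in 26 of 28 cases (Fisher's exact adjusted p = 6.42e-17), among them WRKY75, which rose by 9.02 by the authors' values. The senescence-linked metacaspase MC9, with a deposited value of 3.39, and the immune receptor gene ADR1-L2, at 2.23, lie in the chromosome 5 stretch.

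Genes on the camalexin list were higher in 8 of 10 cases, all 8 of which passed the largest-error test (Fisher's exact adjusted p = 0.000101 for the list). In the authors' table CYP82C2 rose by 10.91, CYP71A12 by 7.91 and CYP71A13 by 5.61. The related indole glucosinolate list shares CYP79B2 and CYP79B3 with the camalexin list. Of the 16 indole glucosinolate genes, 7 were higher (Fisher's exact adjusted p = 0.0336), with deposited rises of 7.69 for the regulator MYB122, 5.23 for CYP79B2 and 1.64 for UGT74B1. Genes of protein folding in the endoplasmic reticulum were higher in 13 of 15 cases (Fisher's exact adjusted p = 4.88e-08), and by the authors' values the chaperone gene BIP3 rose by 3.71, the calreticulin gene CRT3 by 2.45 and BIP2 by 1.84. Immune receptor and signalling genes were higher in 19 of 28 cases (Fisher's exact adjusted p = 2.94e-08), and the danger peptide precursor genes PROPEP2 and PROPEP3 rose by 7.02 and 5.74 and the receptor kinase gene FRK1 by 5.61 in the deposited table.

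Jasmonate and ethylene defence genes were higher in 15 of 26 cases (Fisher's exact adjusted p = 1.75e-05), and the deposited values of PR4, the defensin PDF1.2a and the chitinase PR3 rose by 5.65, 5.64 and 4.21. Among ethylene genes, 6 of 11 were higher (Fisher's exact adjusted p = 0.0172), a list call that ended at a corrected genotype p under 0.01 (5 genes, adjusted p = 0.0679) and with the largest-error test. The ethylene synthesis gene ACS2 rose by 9.12 and ERF2 by 1.63 by the authors' values, while ETR2 at 1.77 did not pass. Of 21 genes of oxidative and mitochondrial stress, 9 were higher (Fisher's exact adjusted p = 0.0172, ended with the largest-error test); the alternative oxidase gene AOX1D rose by 7.34, and the deposited values of UGT74E2 at 3.32 and ZAT12 at 3.23 did not pass.

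Photosynthesis genes were lower in 46 of 52 cases (Fisher's exact adjusted p = 5.98e-29), but no more than 5 of them passed the largest-error test, which ended the list call, and for 51 of the 52 the authors' corrected interaction p was under 0.05. The largest-error test is hardest to pass where line differences lie mainly in the apical parts, so its result does not count against the drop. LHCB2.2 fell by 2.06 in the deposited table, and LHCB2.3 at -2.22 and PSAN at -2.15 did not pass. Abscisic acid and dehydration genes were lower in 9 of 17 cases (Fisher's exact adjusted p = 0.00708), with deposited drops that passed for COR15A, which fell by 3.89, and RD22, which fell by 2.83, and a value of -2.72 for COR15B.

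The other lists had no more 2-fold changed genes than the rest at an adjusted Fisher's exact p under 0.05. Chlorophyll synthesis had 6 of 13 genes lower (Fisher's exact adjusted p = 0.0982), with authors' values of -2.23 for DVR, -1.54 for CHLI2 and -1.35 for CHLM, and chlorophyll breakdown had 2 of 7 higher, including SGR1 at 1.82. Autophagy had 5 of 14 higher, with ATG8H at 2.24, ATG7 at 1.89 and ATG8B at 1.34 in the deposited table. Heat shock had 3 of 8 higher, with HSP17.6A at 3.87, HSP17.4 at 2.62 and HSP17.6II at 2.12 as deposited. Among 6 flavonoid genes 3 were lower; the authors' value of FLS1 fell by 2.81, while TT19 stood at -1.55 and PAP2 at 1.80. Aliphatic glucosinolates had 1 of 15 genes higher and 1 lower, and the circadian clock 1 of 10 higher. Among cell type markers, both myrosin cell genes were lower, with deposited values of -1.53 for TGG1 and -1.74 for TGG2 (Fisher's exact adjusted p = 0.177), 2 of 4 epidermis and trichome genes and 1 of 3 phloem genes were lower, 1 of 4 xylem, 1 of 5 guard cell and 1 of 4 cell division genes were higher, and floral genes had 1 higher and 1 lower of 3. None of the 6 listed reference genes was 2-fold changed, and their median in the 4 lines was 0.18, 0.14, 0.31 and 0.09, in the order b'γ, b'γζ, b'γ sid2 and complemented.

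**Figure D3:**
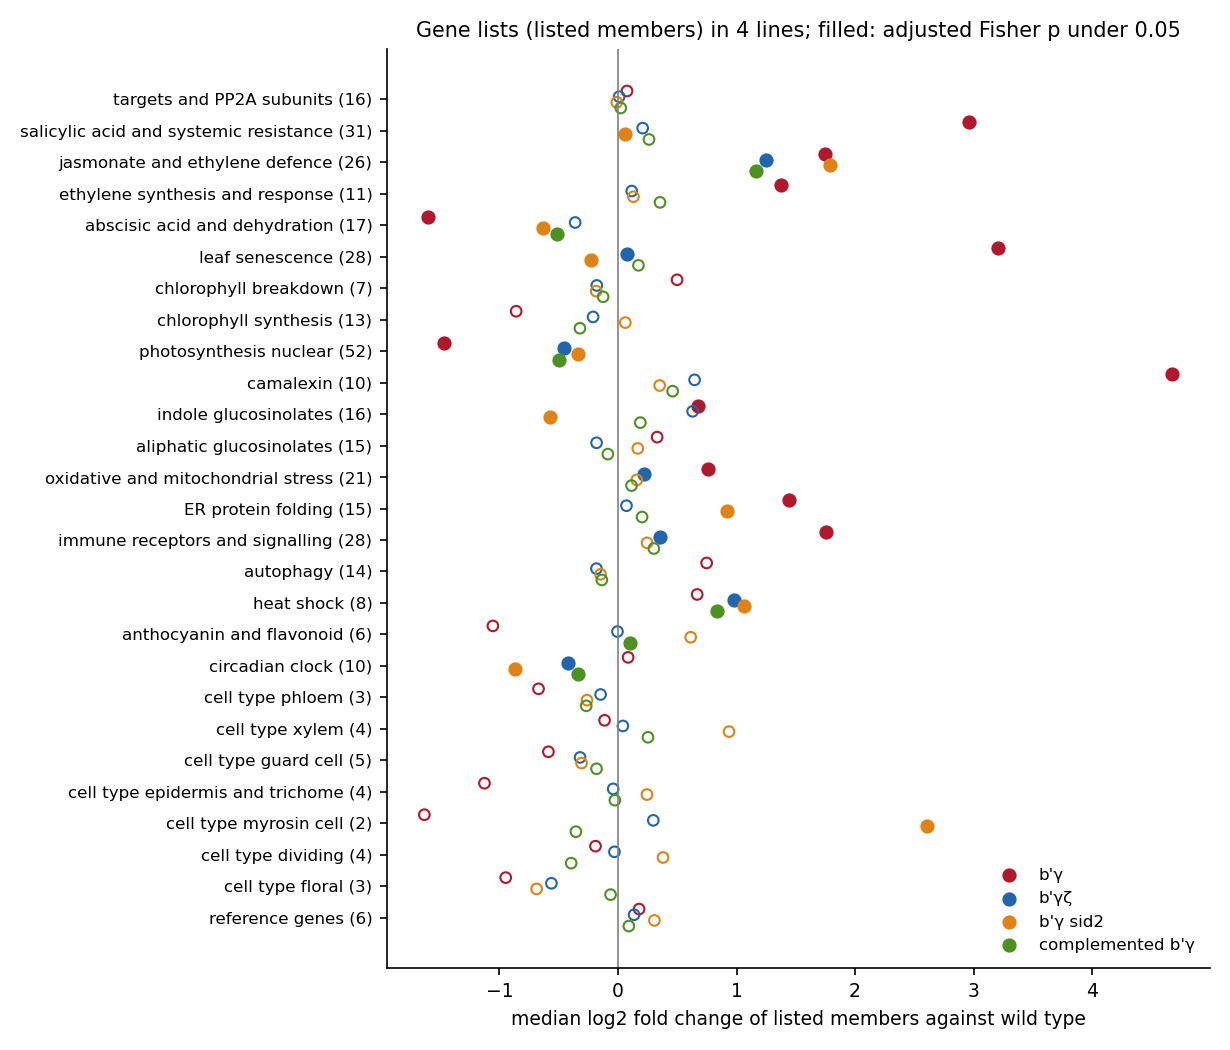
Median log2 fold change against wild type (x axis) of the listed members of each of the 27 gene lists (y axis, members in brackets) in the 4 lines; filled points mark lists with an adjusted Fisher's exact p under 0.05 in either direction. Salicylic acid and senescence genes had medians of 2.96 and 3.21 in b'γ, and the jasmonate list lay above 1 in all 4 lines.

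The comparison of b'γζ with wild type asked what loss of the further subunit left of the b'γ profile. Jasmonate genes were higher, and the clock genes PRR5, PRR9 and CCA1 and the antenna genes LHCB2.1 and LHCB2.2 fell. The same was found in b'γ sid2 and the complemented line, as given below, so none of it was particular to loss of B'ζ. All 4 comparisons share the wild-type pools, and what these pools contributed was not tested for the clock and antenna genes. Against the same pools, b'γ had 1 of 10 clock genes higher and 0 lower, with a smallest value of -0.61. A true rise of clock genes in b'γ could hide an error of these pools, so this does not decide it. The authors' deposited values were 0.80 for PR1, -0.02 for SAG12 and 0.61 for ICS1. Counts were 855 genes higher and 533 lower, of which 214 and 118 passed the largest-error test. Without the chromosome 5 stretch, which held 81 of the higher genes, the counts were 774 and 533, and after centring on the reference genes they were 648 and 737. By the deposited table, the largest rises were 8.78 for the transposable element gene AT5G35935, 5.01 for the transposable element gene AT3G60170, 4.84 for the dehydration-responsive factor gene DDF1 and 4.35 for AT5G28335, with PHI-1 at 4.42 not passing. ATMRD1 fell to -7.28, the neighbouring RING gene AT1G53490 to -4.36 and AT3G22235 to -3.39 in the authors' table, and AT5G59732 at -7.45 and AT4G33467 at -3.45 did not pass.

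Of 26 jasmonate and ethylene defence genes, 15 were higher in b'γζ (Fisher's exact adjusted p = 1.33e-12). JAZ7, a repressor of jasmonate signalling, rose by 4.23 in the deposited table, and PDF1.2a at 4.05 and JAZ8 at 3.95 did not pass. Immune receptor genes were higher in 7 of 28 cases (Fisher's exact adjusted p = 0.0026), with authors' values that rose by 1.62 for PEPR1 and by 1.60 for ADR1-L2, which lies in the chromosome 5 stretch, and stood at 2.31 for PROPEP3. Heat shock genes were higher in 4 of 8 cases (Fisher's exact adjusted p = 0.0026), a call that ended after centring (2 genes, adjusted p = 0.207). As deposited, HSFA2 rose by 3.21 and HSP90.1 by 1.5, and HSP18.2 was at -1.43.

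Clock genes were lower in 3 of 10 cases in b'γζ (Fisher's exact adjusted p = 0.023, and 0.0574 after centring), and by the authors' values PRR5, PRR9 and CCA1 fell to -1.82, -1.43 and -1.16. Photosynthesis genes were lower in 7 of 52 cases (Fisher's exact adjusted p = 0.0159, ended with the largest-error test), among which LHCB2.1 fell to -2.35 and LHCB2.2 to -2.27 and LHCB2.3 was at -1.51 in the deposited table. Senescence genes went both ways, with 5 higher and 5 lower of 28 (Fisher's exact adjusted p = 0.0484 and 0.0159), and neither call held with the largest-error test, nor the higher one after centring (3 genes, adjusted p = 0.41); deposited values were 1.86 for WRKY22, 1.70 for WRKY53 and -1.57 for SAG29. Oxidative stress genes were higher in 5 of 21 cases (Fisher's exact adjusted p = 0.0164, ended with the largest-error test), with ZAT12 at 2.13, WRKY40 at 2.07 and OM66 at 1.28 in the authors' table. Salicylic acid genes had 4 higher and 2 lower of 31 (Fisher's exact adjusted p = 0.214 for higher); UGT74F2 fell by 1.31 as deposited, and GRX480 was at 2.26 and CBP60g at 1.44. Deposited values of the indole glucosinolate genes MYB34, SOT16 and CYP79B3 were 1.3, 1.16 and 1.01 (3 of 16 higher, Fisher's exact adjusted p = 0.164).

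Set against b'γ, the double mutant b'γζ had 2520 genes higher and 2640 lower, of which 817 and 1130 passed the largest-error test; centred on the reference genes the counts were 3264 and 2260. These differences were computed from pairs of deposited values. DIOX1 fell to -13.24, SAG12 to -13.04, DIN2 to -11.62, CYP82C2 to -10.25, ACS2 to -9.02, MYB122 to -8.26, FMO1 to -8.19, WRKY75 to -7.99 and PR1 to -7.63. CYP71A12 fell to -7.01, PROPEP2 to -6.66, AOX1D to -6.50, CYP71A13 to -5.74, FRK1 to -5.67, DLO1 to -5.43, PR4 to -4.91, CYP79B2 to -4.44, CRK7 to -3.61, BIP3 to -3.42 and HSP17.4 to -3.18. ICS1 fell to -2.57 and B'ζ to -2.2, and B'γ differed by 0.24. AT5G35935 rose by 7.19, the MYB gene PFG3 by 5.21, FLS1 by 3.42, COR15A by 3.33, HSFA2 by 2.87, RD22 by 2.38 and MYB34 by 2.12, and AT1G54700 at 5.66 did not pass. Among the lists, senescence was lower in 24 of 28 genes (Fisher's exact adjusted p = 2.02e-15), salicylic acid in 24 of 31 (8.31e-14 by the same exact test), protein folding in 13 of 15 (8.51e-09), immune receptors in 14 of 28 (6.26e-05) and camalexin in 7 of 10 (0.000573). Photosynthesis was higher in 26 of 52 genes (Fisher's exact adjusted p = 1.38e-08), but 2 of these passed the largest-error test, which ended the call, and abscisic acid genes in 8 of 17 (0.0135). Ethylene genes were lower in 6 of 11 cases and oxidative stress genes in 8 of 21 (Fisher's exact adjusted p = 0.00989 and 0.0258), and both calls ended with the largest-error test and after centring. Jasmonate genes had 2 higher and 6 lower of 26, and JAZ7 stood 2.51 above b'γ without passing.

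The comparison of b'γ sid2 with wild type asked what remained when the salicylic acid synthesis gene was also mutated. Jasmonate genes were higher, and senescence, clock and indole glucosinolate genes were lower. In the authors' deposited table the defensins PDF1.2c and PDF1.2a rose by 8.77 and 8.74, the vegetative storage protein gene VSP1 by 6.80 and the oxygenase gene AT2G38240 by 6.17, and PDF1.3 at 5.86 did not pass. The galactinol synthase gene AtGolS3 fell to -4.98, the kinase gene CIPK20 to -4.33 and the thaumatin-like gene AT1G20030 to -4.27 as deposited, and PR1 at -4.32 and the ATPase gene AT3G28510 at -4.08 did not pass. SAG12 had a deposited value of -0.02. Counts were 1194 higher and 1014 lower, of which 457 and 463 passed the largest-error test. They were 1107 and 1013 without the chromosome 5 stretch, and 688 and 1788 after centring on the reference genes.

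In b'γ sid2, 22 of 26 jasmonate genes were higher (Fisher's exact adjusted p = 2.36e-21). Salicylic acid genes were lower in 7 of 31 cases (Fisher's exact adjusted p = 0.00882, ended with the largest-error test), with authors' values of -3.69 for WRKY38 and -3.38 for UGT76B1, and higher in 6 (adjusted p = 0.0754, and 0.0383 after centring with 5 genes). Senescence genes were lower in 11 of 28 cases (Fisher's exact adjusted p = 3.61e-06); NAC046 fell to -2.32 and GLN1;4 to -2.07 in the deposited table, and ORE1 was at -2.38. Indole glucosinolate genes were lower in 6 of 16 cases (Fisher's exact adjusted p = 0.0013), and by the authors' values CYP81F2 fell by 2.26 while MYB34 and CYP79B3 rose by 2.19 and 2.07. Clock genes were lower in 5 of 10 cases (Fisher's exact adjusted p = 0.0013), with deposited drops in PRR5, which fell by 2.90, PRR9, which fell by 2.76, and CCA1, which fell by 2.04.

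Photosynthesis genes were lower in 9 of 52 cases and abscisic acid genes in 5 of 17 (Fisher's exact adjusted p = 0.00937 for each), and both calls ended with the largest-error test. In the authors' table LHCB2.1 fell to -3.0, LHCB2.2 to -2.64, COR47 to -2.55 and RD29A to -2.54, and LHCB1.2 was at -1.63 and RD29B at -2.68. Protein folding genes were higher in 7 of 15 cases (Fisher's exact adjusted p = 0.000277), but 1 passed the largest-error test and after centring 2 were higher (adjusted p = 0.417); deposited values were 2.33 for BIP3, 1.47 for BIP2 and 1.24 for CRT3. Heat shock genes were higher in 5 of 8 cases (Fisher's exact adjusted p = 0.00051), and HSFA2 rose by 2.36, HSP90.1 by 1.62 and HSP101 by 1.39 as deposited. Immune receptor genes had 5 of 28 higher (Fisher's exact adjusted p = 0.15), where the authors' values of PEPR2 and RLP23 rose by 2.06 and 1.56 and CRK7 was at 1.31. Oxidative stress genes had 3 of 21 higher, with ZAT12 at 1.99, GSTF8 at 1.09 and WRKY40 at 1.05 in the deposited table. The myrosin cell genes TGG2 and TGG1 had deposited values of 3.15 and 2.07 (Fisher's exact adjusted p = 0.0289), and neither passed the largest-error test.

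Against b'γ, the b'γ sid2 line had 2929 genes higher and 2878 lower, of which 1223 and 1364 passed the largest-error test; centred on the reference genes the counts were 3112 and 2770. DIOX1 fell to -13.24, SAG12 to -13.04, PR1 to -12.75, DIN2 to -11.79, CYP82C2 to -10.92, ACS2 to -8.99, MYB122 to -8.76, WRKY38 to -7.78, AOX1D to -7.74, WRKY75 to -7.61 and CYP71A12 to -7.16. PROPEP2 fell to -6.71, FRK1 to -6.43, UGT76B1 to -6.34, PROPEP3 to -5.90, CYP71A13 to -5.47, ICS1 to -4.15, CYP79B2 to -3.64, PRR5 to -3.33, MAM3 to -3.0, HSP17.4 to -2.90, PRR9 to -2.87 and CCA1 to -1.76. The transposable element gene AT5G35935 rose by 7.12, the cellulose synthase-like gene ATCSLA01 by 6.56, the amine oxidase gene AT1G31690 by 6.13, FLS1 by 4.65, MYB34 by 3.01, COR15A by 2.81, RD22 by 2.63, RBCS1B by 2.14 and HSFA2 by 2.03. Senescence was lower in 27 of 28 genes (Fisher's exact adjusted p = 1.31e-19), salicylic acid in 27 of 31 (4.49e-17 by the same exact test), immune receptors in 17 of 28 (7.49e-07), camalexin in 8 of 10 (8.6e-05), indole glucosinolates in 8 of 16 (0.00669) and the clock in 5 of 10 (0.0473). Oxidative stress genes were lower in 10 of 21 cases (Fisher's exact adjusted p = 0.00335, ended with the largest-error test). Protein folding was lower in 3 of 15 genes (Fisher's exact adjusted p = 0.829), where CRT3 fell to -1.21 and BI-1 to -1.15. Photosynthesis was higher in 32 of 52 genes (Fisher's exact adjusted p = 4.02e-12) and jasmonate defence in 11 of 26 (0.0119), with 3 genes of each past the largest-error test, which ended both calls. Of the jasmonate genes, PDF1.3, PDF1.2b and PDF1.2c stood 5.24, 4.91 and 4.88 above b'γ without passing. All 4 listed epidermis and trichome markers rose (Fisher's exact adjusted p = 0.00898), with 1.78 for FDH, 1.70 for ATML1 and 1.66 for GL2, and the myrosin cell genes TGG1 and TGG2 rose by 3.60 and 4.89 (adjusted p = 0.139 for that list).

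The complemented line was set against wild type to ask how far the transgene brought the profile back. It had 480 genes higher and 405 lower, of which 52 and 79 passed the largest-error test, and jasmonate genes were higher. The authors' deposited values were -0.12 for PR1, 0.14 for SAG12 and 0.32 for ICS1. Centred on the reference genes, the counts were 388 and 523, and without the chromosome 5 stretch 479 and 403. The highest and lowest deposited values were those of genes named above: AT5G35935 rose by 8.88, and AT5G59732 at -7.45 did not pass. Of other genes named above, ATMRD1 fell to -6.35 and AT1G53490 to -4.09. Of the genes not already named, the largest deposited values were 3.74 for CYP94B1 and 3.41 for CYP94B3, which inactivate jasmonoyl-isoleucine, 3.44 for JAZ10, 3.42 for ATGSTU6 and 3.31 for PRN, none of which passed the largest-error test. AT1G49500 fell to -4.19 and B'η to -3.28 in the authors' table, and AT1G35110 at -4.69, AT1G06002 at -2.98 and AT4G10695 at -2.84 did not pass.

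Jasmonate genes were higher in 15 of 26 cases in the complemented line (Fisher's exact adjusted p = 2.61e-16), of which 2 passed the largest-error test; by deposited values JAZ5 rose by 2.36, and JAZ7 was at 2.48. Heat shock genes were higher in 4 of 8 cases (Fisher's exact adjusted p = 0.000412), and in the authors' table HSFA2 rose by 2.93, HSP90.1 by 1.57 and HSP70 by 1.24. Photosynthesis genes were lower in 12 of 52 cases (Fisher's exact adjusted p = 3.07e-08, ended with the largest-error test); LHCB2.1 fell to -2.59 and LHCB2.2 to -2.48 as deposited, and LHCB2.3 was at -1.98. Clock genes were lower in 3 of 10 cases (Fisher's exact adjusted p = 0.0157), and the authors' values of PRR9 and PRR5 each fell to -1.51 and that of CCA1 to -1.27. Abscisic acid genes were lower in 3 of 17 cases (Fisher's exact adjusted p = 0.047); COR47 fell to -1.46 and RD29A to -1.21 in the deposited table, and RD29B was at -1.74. Flavonoid genes were lower in 2 of 6 cases (Fisher's exact adjusted p = 0.047), a call that ended at a corrected genotype p under 0.01, after centring, with the equal-parts test, without a size limit and with the largest-error test, which neither gene passed. Senescence genes had 2 higher and 2 lower of 28, with WRKY75 at 1.99, DIN6 at -1.75 and SAG29 at -1.26 as deposited, and immune receptor genes had 3 of 28 higher, with authors' values of 1.38 for CRK6, 1.23 for PEPR2 and 1.1 for CRK7.

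Against b'γ, the complemented line had 2347 genes higher and 2759 lower, of which 794 and 1216 passed the largest-error test. Centred on the reference genes the counts were 3356 and 2220, and 78 of the lower genes lay in the chromosome 5 stretch. SAG12 fell to -12.88, DIOX1 to -12.76, DIN2 to -11.62, CYP82C2 to -10.65, PR1 to -8.55, MYB122 to -8.24, ACS2 to -8.04, FMO1 to -7.42, CYP71A12 to -7.36 and WRKY75 to -7.04. PROPEP2 fell to -6.78, AOX1D to -6.43, CYP71A13 to -6.01, FRK1 to -5.41, DLO1 to -5.14, PROPEP3 to -5.00, PR3 and PR4 each to -4.56, B'η to -3.44, BIP3 to -3.35 and ICS1 to -2.85. ATMRD1 fell to -5.91 and AT1G53490 to -4.0, away from wild type as well as from b'γ. AT5G35935 rose by 7.29, AT1G65450 by 5.22, COR15A by 2.90, HSFA2 by 2.59, RD22 by 2.26, RBCS1B by 1.85 and CHLG by 1.14. Senescence was lower in 26 of 28 genes (Fisher's exact adjusted p = 3.22e-18), salicylic acid in 25 of 31 (1.12e-14 by the same exact test), immune receptors in 18 of 28 (4.21e-08), protein folding in 12 of 15 (2.77e-07, and 0.108 after centring with 5 genes) and camalexin in 8 of 10 (4.97e-05). Photosynthesis was higher in 22 of 52 genes (Fisher's exact adjusted p = 3.54e-06), of which 3 passed the largest-error test, which ended the call. Oxidative stress genes were lower in 9 of 21 cases (Fisher's exact adjusted p = 0.00961), which ended with the largest-error test and after centring (7 genes, adjusted p = 0.0524). Jasmonate genes were lower in 7 of 26 cases (Fisher's exact adjusted p = 0.233).

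Without a size limit, where every listed gene counts by its sign, further lists passed. Autophagy was higher in 14 of 14 genes in b'γ (Fisher's exact adjusted p = 0.000338) and lower than in b'γ in all 14 in each of b'γζ, b'γ sid2 and the complemented line (0.00045, 0.000454 and 0.000433), with medians of 0.75 against wild type and -0.80, -0.83 and -0.76 against b'γ. Protein folding was lower than in b'γ in 15 of 15 genes in b'γ sid2 (Fisher's exact adjusted p = 0.00029, median -0.59), and higher than wild type in 15 of 15 in the complemented line (0.000342, median 0.20). Chlorophyll synthesis was lower in 12 of 13 genes in b'γ and higher than b'γ in 12 in b'γ sid2 (Fisher's exact adjusted p = 0.0183 and 0.0167). Ethylene genes were lower than in b'γ in 11 of 11 cases in b'γ sid2 and the complemented line (Fisher's exact adjusted p = 0.00283 and 0.00272), and indole glucosinolate genes in 14 of 16 in the complemented line (0.00896). In b'γζ camalexin was higher in 9 of 10 genes and indole glucosinolates in 13 of 16 (Fisher's exact adjusted p = 0.0486 for each), and in the complemented line immune receptors in 26 of 28 (3.02e-05).

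Other calls at the 2-fold limit ended when signs alone were counted. In b'γ these were higher ethylene and indole glucosinolate and lower abscisic acid genes, in b'γζ senescence in both directions, higher oxidative stress and heat shock and lower clock genes, and in the complemented line higher heat shock and lower abscisic acid and flavonoid genes. In b'γ sid2 they were higher heat shock and myrosin cell and lower salicylic acid, abscisic acid, senescence, photosynthesis, indole glucosinolate and clock genes. Against b'γ they were higher abscisic acid genes in b'γζ and higher jasmonate and epidermis and trichome genes in b'γ sid2. The smallest Fisher's exact adjusted p among these ended calls was 0.0871.

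The authors' interaction test asked, over all 5 genotypes, whether line differences depended on the leaf part. It had a corrected p under 0.05 for 7728 of the 18231 listed genes, or 42.4%, and for 62.5% of the 6048 genes that were 2-fold changed in b'γ against 32.4% of the other listed genes. The 6048 genes were chosen by their apical values in b'γ, which also enter the interaction test. Part of the gap between the 2 shares therefore follows from that choice. By list, the authors' test passed for 51 of 52 photosynthesis genes, 12 of 13 chlorophyll synthesis genes, 12 of 14 autophagy genes, 20 of 28 senescence genes, 9 of 31 salicylic acid genes and 6 of 26 jasmonate genes. For SAG12 the authors' corrected interaction p was 5.54e-24. The leaf part itself had an authors' corrected p under 0.05 for 9869 genes, or 54.1%. Values of basal parts were not used here.

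The last question was how much of the b'γ profile the other lines shared. Of the 3099 genes higher in b'γ, 2541 (82.0%) were less than 2-fold higher in b'γζ, 2488 (80.3%) in b'γ sid2 and 2757 (89.0%) in the complemented line. By the direct difference, 995, 1035 and 1100 of the 3099 were lower than in b'γ past the largest-error test, in the same order of lines. The median log2 fold change of all 3099 was 1.94 in b'γ, 0.27 in b'γζ, 0.25 in b'γ sid2 and 0.25 in the complemented line. Of the 2949 genes lower in b'γ, 2614, 2454 and 2664 were less than 2-fold lower in b'γζ, b'γ sid2 and the complemented line, and 654, 807 and 668 were higher than in b'γ past the largest-error test. Both sets of genes were chosen by their values in b'γ, so part of the smaller changes in the other lines follows from that choice. The 3 direct differences also share the b'γ pools, so they are not independent of each other. Genes changed in the same direction as in b'γ numbered 893 in b'γζ, 1106 in b'γ sid2 and 627 in the complemented line, and 86, 246 and 37 genes were changed in opposite directions. In all 4 lines 179 genes were higher and 117 lower, where simulated unchanged lines gave 9.92 and 10.1 on average with the equal-parts error and 305 and 299 with the largest error that the authors' p-values allow. With independent calls 145 higher and 86.2 lower genes would be shared by b'γ and b'γζ, where 558 and 335 were. All 4 comparisons used the same wild-type pools, so errors in those pools are shared: simulated lines with no change shared 74.4 genes on average, and at most 99, between b'γ and b'γζ with the error of the equal-parts test, and 1365 on average with the largest error that the authors' p-values allow. Between b'γ and the complemented line the largest error gave 1366 on average, more than the 480 higher and 405 lower genes of that line together. The largest error thus cannot hold for all genes at once. The simulations with it, also those for all 4 lines, therefore decide nothing about the shared genes. Across genes, which are not independent replicates, Pearson's r with b'γ was 0.42 for b'γζ, 0.29 for b'γ sid2 and 0.46 for the complemented line, where simulated unchanged lines gave 0.50. That 0.50 follows from the shared wild-type pools and holds for lines without changes of their own. Changes in b'γ alone lower r, so values under 0.50 do not mean that these lines share less than unchanged lines would. Between the other lines r was 0.66 for b'γζ and b'γ sid2, 0.73 for b'γζ and the complemented line and 0.65 for b'γ sid2 and the complemented line. The covariance of the log2 fold changes with b'γ was 0.36 for b'γζ, 0.31 for b'γ sid2 and 0.33 for the complemented line, against 0.04 in the simulation with the equal-parts error. The authors' p-values alone allow shared wild-type error to bring a covariance between 0.03 and 0.76, a range that includes all 3. Shared error would, however, add the same covariance to every pair of lines. For the other pairs, in the order of their r above, the covariance was 0.26, 0.19 and 0.22, all below the 3 with b'γ. These values argue against shared error near the upper end of that range. No interval of a covariance was computed, so the size of an excess over shared error was not established.

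**Figure D4:**
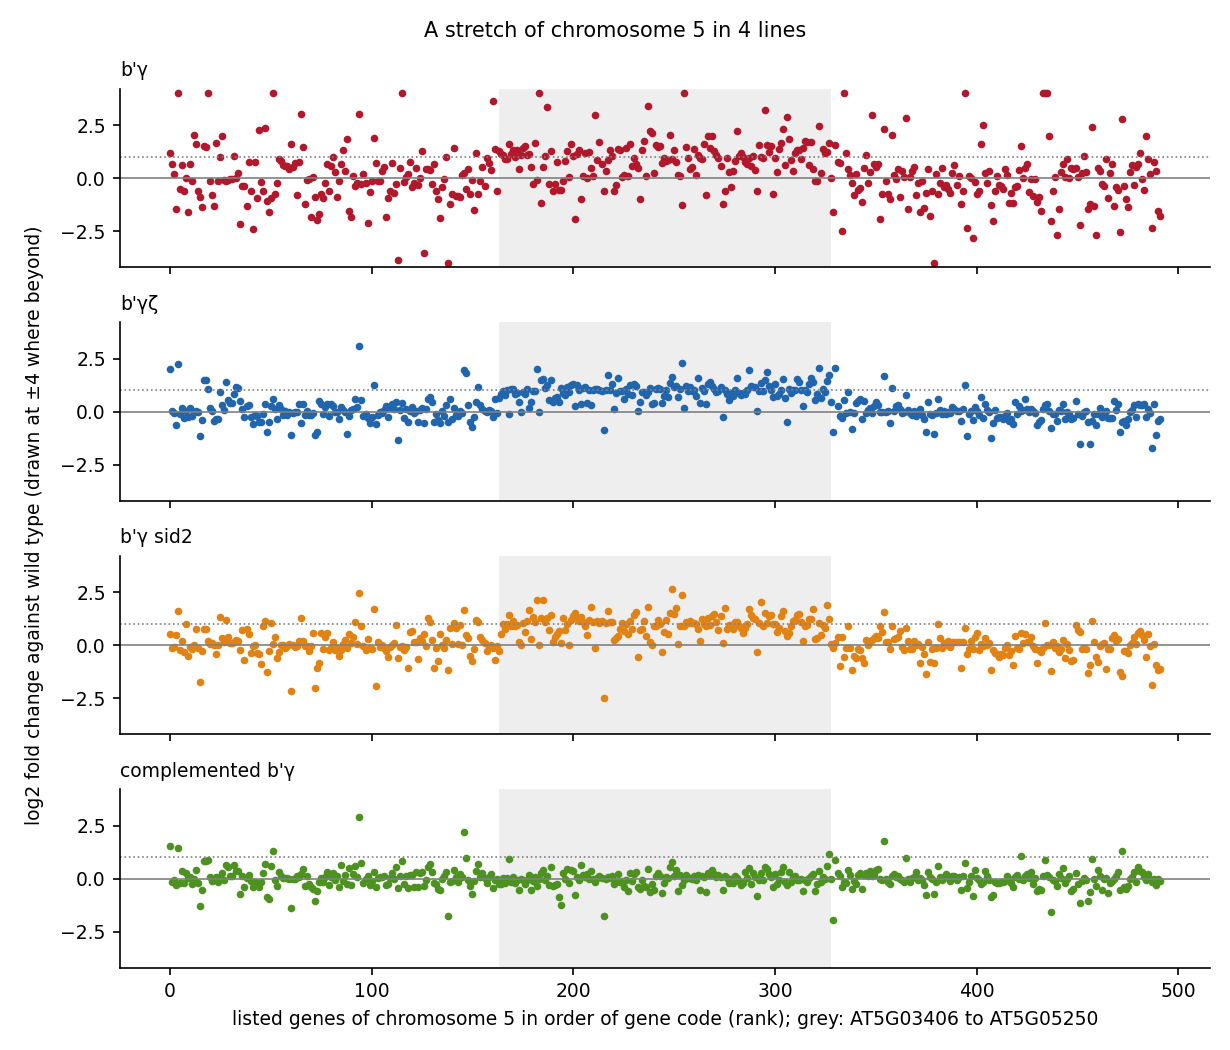
The authors' deposited log2 fold change against wild type (y axis) of the listed genes of chromosome 5 in order of gene code (x axis, rank), with the 164 genes of the stretch shaded and 164 listed genes on each side, in 1 panel per line; values beyond 4 are drawn at 4. The stretch lies near 1 in b'γ, b'γζ and b'γ sid2, with medians of 0.96, 1.0 and 1.02, and near 0 in the complemented line.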

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

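All counts in this part rest on the authors' interaction test, which was taken up after the table had been seen. What singled these results out is that, by that test, the differences between the 5 genotypes were not the same in apical and basal parts; values of basal parts were not used here, so no direction is given and no explanation is weighed. The authors' corrected interaction p was under 0.05 for 7728 of the 18231 listed genes, or 42.4%. This p was also under 0.05 for 72 of the 158 genes that the rule for named genes took, a share near that of all listed genes. For SAG12 it was 5.54e-24.

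Among chloroplast-related lists the authors' test passed for 51 of 52 photosynthesis genes, 12 of 13 chlorophyll synthesis genes and 6 of 7 chlorophyll breakdown genes, and among lists of leaf ageing and stress for 20 of 28 senescence, 12 of 14 autophagy, 13 of 17 abscisic acid and 9 of 21 oxidative stress genes. Among defence lists it passed for 9 of 31 salicylic acid, 6 of 26 jasmonate, 3 of 11 ethylene, 16 of 28 immune receptor, 3 of 10 camalexin, 3 of 16 indole glucosinolate and 3 of 15 aliphatic glucosinolate genes. It passed for 3 of 15 protein folding, 3 of 8 heat shock, 1 of 6 flavonoid and 2 of 10 clock genes, for 4 of 16 targets and PP2A subunits and for 2 of 6 reference genes. Among cell type markers it passed for 1 of 3 phloem, 1 of 4 xylem, 1 of 5 guard cell, 3 of 4 epidermis and trichome, 1 of 2 myrosin cell and 1 of 3 floral genes. No list was tested against the 42.4% of all listed genes. Each defence list but that of immune receptors had a smaller share than this, as had protein folding, heat shock, flavonoid and clock genes.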

How the results depend on the processing

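The largest-error and equal-parts tests, centring and leaving out the chromosome 5 stretch were chosen after seeing the data; no size limit was the reading planned first, replaced once the table was seen; a corrected p under 0.01 and adjustment over listed genes were planned, and under these, and without the stretch, all 25 counts compared (genes per comparison, shared genes, list calls) stayed within 1.5 times. Counts are given as higher and lower, in the order b'γ, b'γζ, b'γ sid2 and complemented against wild type, then b'γζ, b'γ sid2 and complemented against b'γ. Without a size limit, which takes every listed gene, they were 9254 and 8930, 8685 and 9327, 9438 and 8570, 9007 and 8997, then 8997 and 9177, 8858 and 9329, 8894 and 9298; 11878, 10691 and 12231 genes shared their direction with b'γ, and list calls moved to 1 lower for b'γζ, 2 higher and 0 lower for b'γ sid2 and 2 lower for the complemented line. The largest-error test, which adds a criterion, gave 1442 and 1164, 214 and 118, 457 and 463, 52 and 79, then 817 and 1130, 1223 and 1364, 794 and 1216; shared genes were 144, 339 and 55, and list calls moved to 1 lower for b'γ, 3 higher and 1 lower for b'γζ, 2 higher and 3 lower for b'γ sid2 and 2 lower for the complemented line. The equal-parts test gave 537 and 295 for b'γζ and 195 and 211 for the complemented line, 485 and 273 genes shared with b'γ in these lines, and 3 lists higher in b'γζ. Centring gave 688 and 1788 for b'γ sid2 and 3 lists higher in b'γζ; the 6 reference genes were themselves chosen into the table by a genotype difference, and why their medians lie above 0 was not tested. No named value with a call changed sign. Which direction had more genes did turn after centring in 6 of the 7 comparisons, with 2621 and 3685 for b'γ, 648 and 737 for b'γζ, 688 and 1788 for b'γ sid2 and 388 and 523 for the complemented line, then 3264 and 2260 for b'γζ and 3356 and 2220 for the complemented line against b'γ; it also turned in 3 with the largest-error test, 2 without a size limit and 1 with the equal-parts test (complemented line), and the cause was not tested. Of 356 values of named genes, 4 lost their call at a corrected p under 0.01, 127 with the largest-error test and 10 after centring, where 2 gained one. Not run, since they need values per library or levels, were DESeq2 size factors and its test, the count filters, the fit of 10 libraries alone, the replicate block, leave-one-out, the pseudocount, the low-value and low-level filters, the estimated camera correlation and matching in 20 bins; other splits of the samples could not be run either. No paired analysis was possible because the values used hold none per library. The labels pair the apical and basal parts of the same leaves within a genotype. The authors' p-values were read with 40 residual degrees of freedom, which leave no term for this pairing. What the pairing would change in the listed genes, the interaction counts or the largest-error test was not tested. Depth is unknown, so what it limits cannot be stated.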

Other observations

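The gene families and the tests of the 3 patterns in this part were chosen after the results were seen, except the share of genes listed in the chromosome 5 stretch and the neighbours of B'η, which were fixed before those values were computed.

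Among 11 further gene families, tested with one-sided Fisher's exact tests adjusted over families and lines, those of defence signalling were higher in b'γ. WRKY transcription factor genes were at least 2-fold higher in 38 of 58 cases (exact adjusted p = 1.07e-14, median log2 fold change 1.79), cysteine-rich receptor-like kinases in 25 of 38 (6.35e-10), disease resistance genes of the NLR class in 36 of 97 (1.78e-05) and berberine bridge enzyme genes in 13 of 18 (5.18e-06). In b'γζ the WRKY genes were higher in 13 of 58 cases (exact adjusted p = 1.89e-05), none of which passed the largest-error test, NLR genes in 15 of 97 (0.000322, 7 past it), cysteine-rich receptor-like kinases in 8 of 38 (0.00139, 3 past it) and berberine bridge enzyme genes in 6 of 18 (0.000584, none past it). Berberine bridge enzyme genes were also higher in 7 of 18 cases in b'γ sid2 (exact adjusted p = 0.000468, 1 past the largest-error test) and 3 in the complemented line (0.0441, none past it), as were cysteine-rich receptor-like kinases in 7 of 38 there (0.000328, none past it). WRKY genes were higher in 4 cases and lower in 5 in b'γ sid2, and higher in 4 in the complemented line.

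Families of growth and the chloroplast were lower in b'γ. SAUR auxin-responsive genes were at least 2-fold lower in 25 of 44 cases (exact adjusted p = 3.94e-08), arabinogalactan protein genes in 22 of 38 (1.26e-07), expansin genes in 7 of 12 (0.00942) and plastid-type ribosomal protein genes in 16 of 36 (0.000652, median -0.98, none past the largest-error test). Tubulin genes were lower in 6 of 15 cases (exact adjusted p = 0.131). SAUR genes were also lower in 6 of 44 cases in b'γζ and 7 in the complemented line (exact adjusted p = 0.0105 and 0.000652), and arabinogalactan protein genes in 5 of 38 in the complemented line (0.0105), none of them past the largest-error test. Of 137 cytosolic ribosomal protein genes 3 were higher and 2 lower in b'γ, and none of 22 proteasome subunit genes was 2-fold changed there.

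The 164 listed genes from AT5G03406 to AT5G05250 on chromosome 5 had a median log2 fold change of 0.96 in b'γ (95% bootstrap interval 0.87 to 1.09), 1.0 in b'γζ (0.95 to 1.04) and 1.02 in b'γ sid2 (0.94 to 1.07), while medians of the flanking genes lay between -0.14 and 0.03. Low values in the shared wild-type pools are argued against by the median of 0.00611 in the complemented line. The symptomatic state of b'γ is argued against by b'γζ and b'γ sid2, lines in which PR1 and SAG12 did not rise. Their highest windows, 1.08 and 1.1, lay in the stretch, and no window of 200 shuffles was as high. The smaller of their medians, 1.0, decides nothing here, since the stretch was bounded by its high values in these lines. A gain of 1 copy per copy of the stretch cannot be told apart from other reasons for higher transcripts there: the 1.0 is the value that prompted it, and the share of its protein-coding genes that the table lists, 159 of 203 or 78.3% and above that of 99.1% of other stretches of as many genes, follows from any of them, since the stretch was found by its changed genes. An effect of the B'γ mutation on these genes stays open as untested, since the stretch was higher in the 3 lines that the labels give as mutant without the transgene.

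Jasmonate and ethylene defence genes had medians of 1.75 in b'γ, 1.25 in b'γζ, 1.79 in b'γ sid2 and 1.16 in the complemented line, and 10 of 26 were at least 2-fold higher in all 4. Scaling of the libraries is argued against, since the list lay at least 1.07 above the reference genes in every line. Loss of B'γ as the whole cause is argued against, as far as the transgene restores B'γ, by the median of 1.16 in the complemented line (95% bootstrap interval 0.69 to 1.56), whose B'γ value was 0.35. That interval resamples genes and leaves out errors of the pools that the genes share. The argument thus holds only as far as such errors are small. In this line 2 of the 15 higher members passed the largest-error test. Low values in the shared wild-type pools as the whole cause in all 4 lines are argued against by 6 of the 26 members, which differed from b'γ past the largest-error test in another line. Each of these differences is with b'γ, so they do not decide the cause in the other lines. The median of b'γ sid2 minus the complemented line, 0.059 (-0.36 to 1.96, centred on the reference genes), decides nothing, since 13 members were higher and 13 were not. Nor do the SDs between lines, over 0.25 for all 26, since they include an unknown error of each line. For the part common to all 4 lines, as in the smallest median of 1.16, low values in these pools cannot be told apart from a true difference, since all 4 comparisons use the same pools.

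B'η had a log2 fold change of -3.28 in the complemented line alone. Reads of the transgene assigned to its paralogs would raise B'η, against the -3.28 found. A silencing of B' family genes in general is argued against by the median of -0.19 of the other 6 listed B' genes, which ranged from -0.52 to 0.13 without counting B'γ, and a change of the surrounding chromosome by the median of -0.0375 (95% bootstrap interval -0.10 to 0.15) of the 20 nearest listed neighbours. No biological explanation was tested, and a change at B'η itself stays open.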
